A study of Rattus norvegicus with 6 samples.

How the data were processed

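RNA sequencing was analysed from 6 libraries of cultured rat mesenchymal stem cells, 3 labelled rcMSC, whose series title names cranial bone as their origin, and 3 labelled rbMSC, from the marrow of femurs and tibias. Per the labels, total RNA was extracted with a column kit and sequenced as paired reads of 150 nt on a DNBSEQ-G400RS instrument. Per the labels' protocols, the authors trimmed reads with Trim Galore 0.6.7 and Trimmomatic 0.39, mapped them to the rat genome build mRatBN7.2 with STAR 2.7.9a and counted reads in annotated genes with featureCounts 2.0.1. DESeq2 1.20.0 is named in the submitters' processing notes. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. Reads from a gene and an overlapping, antisense or near-identical copy can therefore not be told apart.

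The deposited values are raw counts per gene and library, made by the authors with no normalization. The table also holds a Length column, which per the file headers is part of the counting output and was used only to test for a trend with gene length. It has 30498 genes under Ensembl identifiers, of which 23359 carry a symbol, and no mitochondrial genes. Symbols, positions and gene ontology terms were taken from the deposited table, since none of its identifiers matched the gene name table at hand. Total counts ranged from 21340290 to 26928079 per library, so that 1 count was worth between 0.0371 and 0.0469 CPM (a gene's counts scaled to the size of the library). Where a group had no count, the fold change is given as a bound against a floor of 3 counts over the group, with no interval. For named genes with 1 to 3 counts in a group, the ratio is given with an exact binomial 95% interval, which covers counting error only. List medians were also computed with genes of 3 or fewer counts in a group set at that floor.

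Libraries were grouped by their titles. Nothing in the labels says that the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical. Counts of each pair of libraries were compared by chi-square over genes with at least 20 counts in the pair, and every pair of 1 group differed by more than counting noise.

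The test of rcMSC against rbMSC was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, the default low-count filter of filterByExpr, robust dispersions and Benjamini-Hochberg adjustment over the 14836 genes kept. An adjusted p under 0.05 was the threshold. Fold changes are rcMSC over rbMSC on the log2 scale, and the standard error (SE) given with each is the fold change divided by the square root of its F statistic. CPM values are means ± SD over 3 libraries after TMM scaling.

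A set of 33 gene lists was written down from general knowledge before the data were examined, as were the tests, the alternatives (except those said to be added later) and the rule for naming genes. Of 749 distinct symbols in the lists, 717 were in the table. Lists with 5 or more genes past the filter were tested with camera in limma 3.58.1, at its preset correlation of 0.01 on log2 CPM with a prior count of 2, and adjusted over the 30 lists tested. Camera was repeated with an estimated correlation, and fry tested whether the genes of a list moved, on balance, in 1 direction, without comparing them with other genes. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries and not from the genes, which raises p whatever the correlation. Members past the threshold were counted over all genes and after adjustment over the list alone.

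The rule named the 6 genes that rose and the 6 that fell most, among those past the threshold with a mean log2 CPM of at least 1, no overlap between groups and a settled symbol. It also named up to 2 members of each list with the largest change at a mean log2 CPM of at least 0, or the member with the smallest p where none passed. A fixed set of 5 surface markers (Thy1, Itgb1, Cd44, Ptprc and Itgam) and 5 neurotrophic factors was to be named whatever its values, and of the latter Bdnf, Gdnf, Vegfa and Hgf are given here. All other genes named were chosen after their values were seen.

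On simulated counts with the real means, library sizes and common dispersion, edgeR recovered 10% of genes changed 1.25-fold, 72% of those changed 1.5-fold, 89.8% of those changed 2-fold and 100% of those changed 4-fold, with 8 false calls among 14780 genes tested. Camera found 2 of 2 simulated lists shifted by 0.5 on the log2 scale and called 0 of the unshifted ones. Genes were drawn independently in these simulations, so false calls that come from correlation between genes were not tested.

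Alternatives were other library scalings, other low-count filters, DESeq2 1.42.0, limma voom with sample quality weights, dispersions without robust estimation, the replicate number as a block, and each library left out in turn. After the data were seen, a test against a 1.5-fold change and the removal of a trend on gene length were added. Library properties were compared with exact permutation tests, which cannot go below a p of 0.1 with 3 libraries against 3. Figures were drawn with matplotlib 3.10.9.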

Results

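The series measured gene expression by RNA sequencing in rat mesenchymal stem cells (MSC) of 2 origins. Its title concerns transplantation of cranial bone MSC after spinal cord injury, and its design text names a single comparison, rcMSC (cranial) against rbMSC (femur and tibia marrow), with 3 libraries each. Total counts were 21340290, 23030159 and 25170868 in rbMSC replicates 1 to 3, and 26928079, 26775456 and 26179769 in rcMSC replicates 1 to 3. The question of the comparison was how the expression profiles of the 2 kinds of culture differ.

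Of the gene lists tested, Hox genes, which specify position along the trunk and limbs, had the largest median change, with 18 of 19 lower in rcMSC and a median log2 fold change of -6.44 (-7.14 to -6.04 without 1 library). Of 20 factors that pattern the cranial mesenchyme, 11 were higher in rcMSC, such as Alx4, Zic1, Zic2 and Six2, 2 were lower (Foxc1 and Tbx15) and 7 did not pass the threshold. Most of the pericyte, contractile, cell cycle and macrophage genes were lower in rcMSC. These lists passed camera's threshold at its preset correlation and none passed with an estimated correlation (camera adjusted p = 0.0824 to 0.0945). The estimated correlation was below the preset 0.01 for the pericyte (-0.0622), cranial (-0.0238) and cell cycle (0.00294) lists. For the Hox (0.132), contractile (0.0396) and macrophage (0.0262) lists it was above. For the lists below the preset, the lost call does not come from correlation between members. Of the neurotrophic factors, some such as Ptn, Artn, Igf1 and Bdnf were higher in rcMSC, and others such as Lif, Nrg1 and Il6 were lower.

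Of 14836 genes tested with edgeR, 3351 were higher and 3445 lower in rcMSC, together 45.8%. At least 2-fold changes were found in 854 higher and 1265 lower genes, and at least 8-fold changes in 115 and 165. The 3 libraries of 1 group all lay above the 3 of the other in 8467 genes (57.1%), where chance gives 10%. The median log2 fold change over all genes was 0.015. In a test against a change of 1.5-fold, added after the data were seen, 802 genes were higher and 1213 lower.

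The genes that rose most in rcMSC were Thbs4, Alx1, Zic1, Sfrp2, Tfap2b and Zic2. Thbs4 (ENSRNOG00000012471), a matrix glycoprotein of tendon and muscle, lies on chromosome 2 from 23983158 to 24026313 in mRatBN7.2. Its level was 812 ± 256 CPM in rcMSC and 5.39 ± 1.42 in rbMSC (SD, n = 3 each), a log2 fold change of 7.22 (SE 0.34, edgeR adjusted p = 1.49e-05). Sfrp2 (ENSRNOG00000009465, chromosome 2, 169089517 to 169097063), a secreted modulator of WNT signalling, had 171 ± 13.4 CPM against 1.63 ± 0.30 (log2 fold change 6.70, SE 0.12, edgeR adjusted p = 1.14e-10). Alx1 (ENSRNOG00000004390, chromosome 7, 38147117 to 38177220), a homeobox factor of the developing face, had 25.7 ± 1.59 CPM against 0.181 ± 0.12 (log2 fold change 7.07, SE 0.22, edgeR adjusted p = 4.66e-09). The value for Alx1 was 7.78 without rbMSC replicate 3. The zinc finger factor Zic1 (ENSRNOG00000014644, chromosome 8, 91908576 to 91912731) had a log2 fold change of 6.91 (SE 0.24, edgeR adjusted p = 9.95e-09). Zic2 (ENSRNOG00000054879, chromosome 15, 99576697 to 99581522) had a log2 fold change of 6.46 (SE 0.22, edgeR adjusted p = 9.89e-09). Tfap2b (ENSRNOG00000011823, chromosome 9, 21786258 to 21814520), a factor of the neural crest lineage, had 384 counts in rcMSC and 3 in rbMSC, a ratio of 112 with an interval of 38.1 to 546. Its fitted log2 value moved to 7.46 without rbMSC replicate 3.

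The genes that fell most were all Hox genes. Hoxa9 (ENSRNOG00000064322, chromosome 4, 81323382 to 81326358) had 0.0779 ± 0.08 CPM in rcMSC and 16.5 ± 0.99 in rbMSC, a log2 fold change of -7.68 (SE 0.31, edgeR adjusted p = 2.79e-08). Hoxc10 (ENSRNOG00000016149, chromosome 7, 134103643 to 134108966) had 0.373 ± 0.27 CPM against 48.8 ± 0.60 (log2 fold change -7.04, SE 0.21, edgeR adjusted p = 5.17e-09). Without rcMSC replicate 3 these values were -8.63 for Hoxa9 and -7.76 for Hoxc10. The other 4 had 2 or 3 counts over the rcMSC libraries, so that counting error sets their ratios. Hoxc9 (ENSRNOG00000016199, chromosome 7, 134118817 to 134121492) was 271 times higher in rbMSC, with an interval of 74.7 to 2250. The ratio was 220 (74.9 to 1070) for Hoxc5 (ENSRNOG00000016598, chromosome 7, 134150988 to 134154410) and 170 (57.8 to 828) for Hoxa3 (ENSRNOG00000006281, chromosome 4, 81269243 to 81313218). For Hoxa6 (ENSRNOG00000048917, chromosome 4, 81306407 to 81308850) it was 155 (52.6 to 754). The fitted log2 values of Hoxc9 without rcMSC replicate 2, and of Hoxc5 and Hoxa6 without rcMSC replicate 3, moved to -10.38, -8.48 and -7.97, and depend on the prior count.

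Of the 19 Hox genes with enough counts, 18 were lower in rcMSC, and 18 when adjusted over the list alone. Hoxa2 was the exception, at -0.72 (edgeR adjusted p = 0.33). The list's camera adjusted p was 1.38e-12, and the adjusted p = 0.0834 with an estimated correlation. With the 6 genes of 3 or fewer rcMSC counts set at the floor of 3 counts over the group, the list's median was -5.95. Summed over their genes, the Hoxc cluster had 161 CPM in rbMSC and 1.33 in rcMSC, and the Hoxa cluster 48.1 and 1.12. The Hoxd cluster had 15.8 and 2.95. No Hoxb gene passed the low-count filter in these cultures, with 24 counts in all in rbMSC and 56 in rcMSC.

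**Figure D1:**
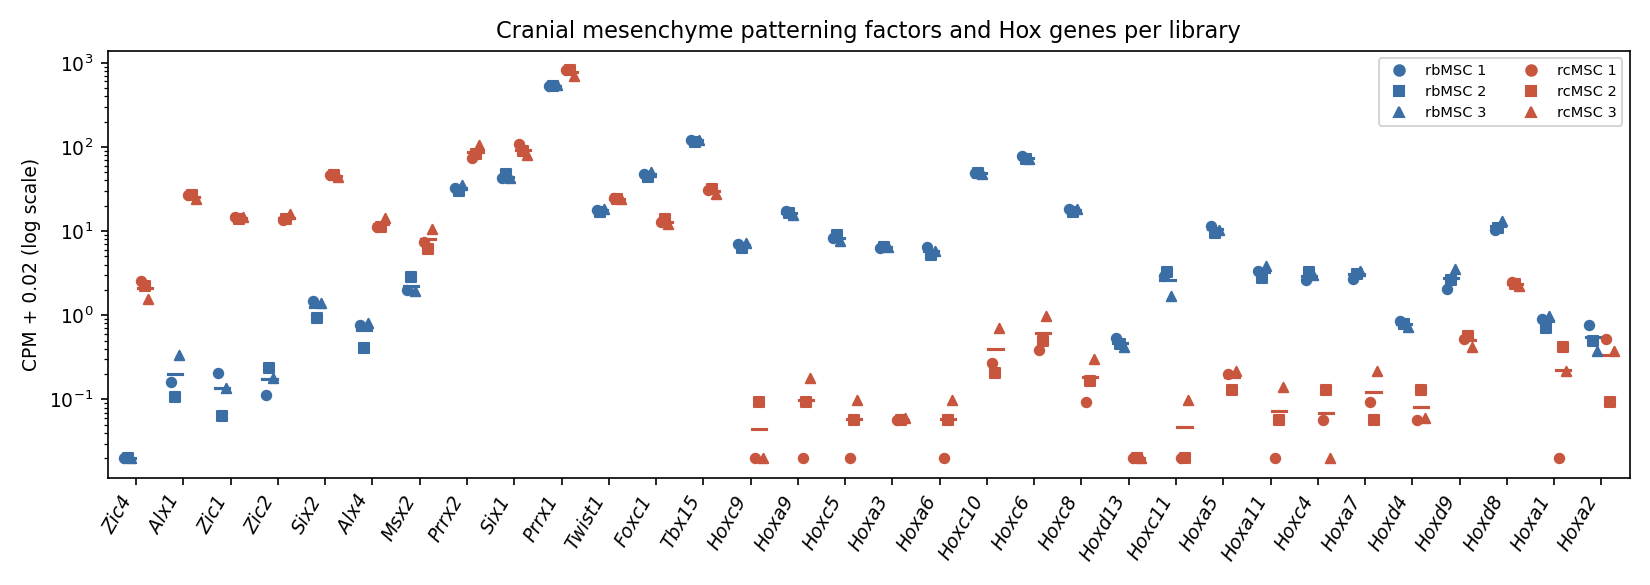
CPM plus 0.02 on a log axis for the cranial mesenchyme patterning factors past the threshold and all 19 Hox genes tested, each point 1 library and each bar the mean of 3. The 3 rcMSC libraries lie below the 3 rbMSC libraries for the 18 Hox genes past the threshold, and points at the lower edge are libraries with no count.

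Among the 20 cranial mesenchyme patterning factors tested, 11 were higher and 2 lower in rcMSC, and 11 and 2 when adjusted over the list alone. The median log2 fold change was 0.61, also with Zic4 at its bound, with a camera adjusted p = 0.00237, and the adjusted p = 0.0945 with an estimated correlation. Zic4 had 168 counts in rcMSC and 0 in rbMSC, at least 49-fold higher against a floor of 3 counts over the group. Six2 and Alx4 rose by log2 fold changes of 5.18 and 4.24. Foxc1 and Tbx15 were the 2 that fell, by log2 fold changes of -1.87 and -2.00. Of 15 neural crest transcription factors, 5 were higher, with Zic1, Msx2, Myc and Twist1 among them, and 4 lower, 5 and 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.523). Limb identity factors also moved both ways, 4 higher and 7 lower of 15, 4 and 7 over the list alone (camera adjusted p = 0.523). Pitx1, a hindlimb factor, had 299 counts in rbMSC and 3 in rcMSC, a ratio of 114 with an interval of 38.6 to 555. Its fitted log2 value moved to -7.52 without rcMSC replicate 3. Hand2 fell by a log2 fold change of -4.55 (edgeR adjusted p = 0.000344), or -6.28 without rcMSC replicate 2. En1, Irx3, Irx5 and Meis2 were the 4 limb list members that rose, by 2.31, 1.42, 1.16 and 1.08.

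**Figure D2:**
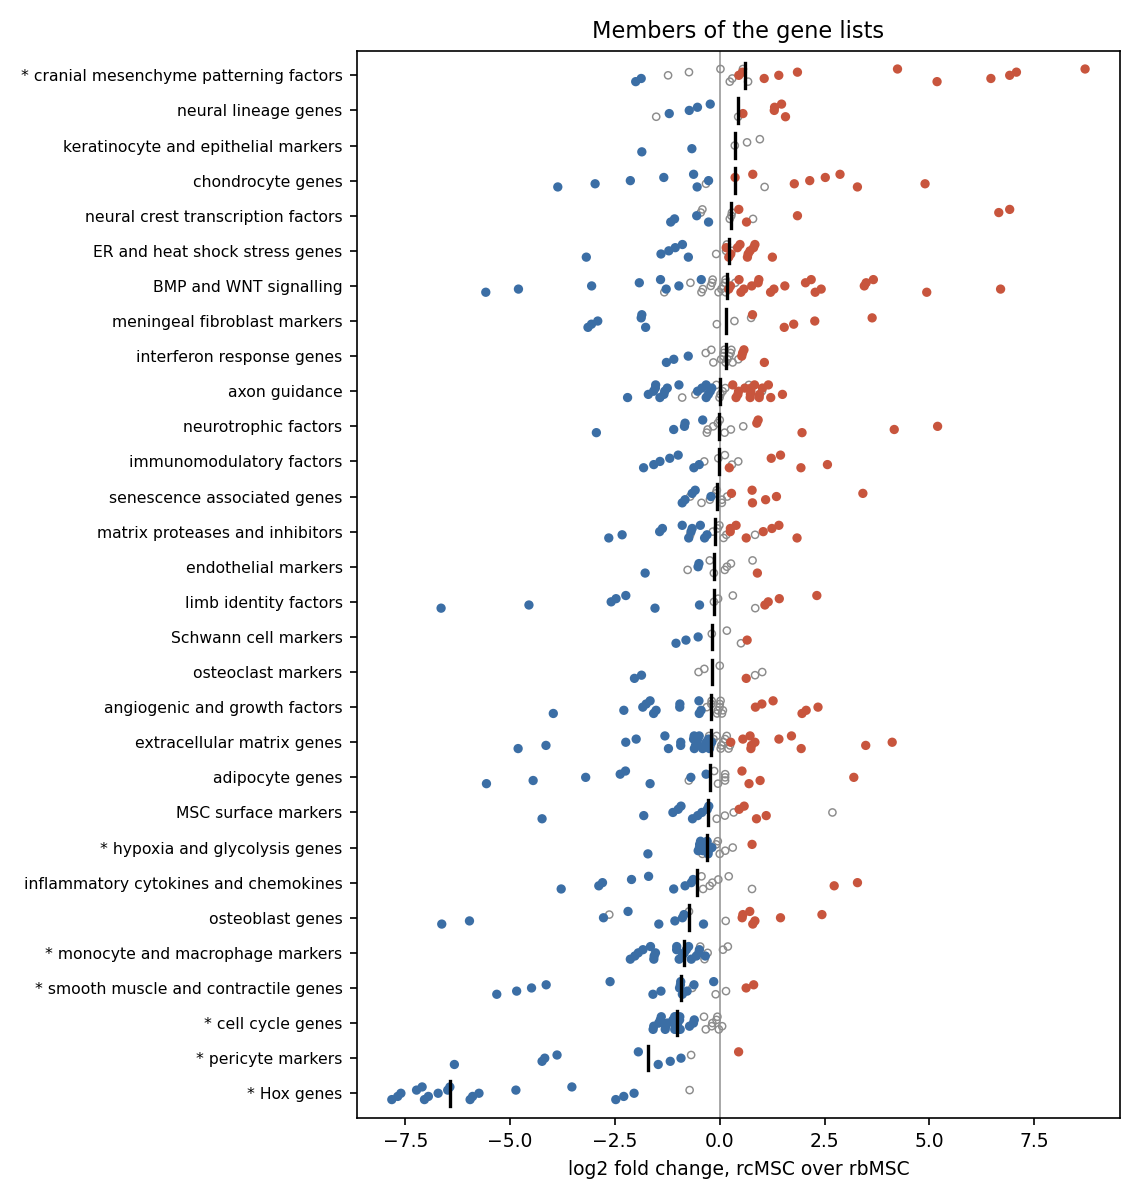
Log2 fold changes (rcMSC over rbMSC) of the members of each list tested, filled where past the threshold and open where not, with the list median as a bar. Asterisks mark the 7 lists with a camera adjusted p under 0.05 at the preset correlation (0 with an estimated correlation), of which the Hox list has the lowest median, -6.44, and the cranial list the highest, 0.61.

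Neurotrophic factors, proteins that support neurons, went both ways. Of 18 tested, 5 were higher and 5 lower in rcMSC, 5 and 5 when adjusted over the list alone, and the list as a whole did not pass (camera adjusted p = 0.808). Ptn (pleiotrophin) rose from 0.917 ± 0.26 to 33.3 ± 5.64 CPM (log2 fold change 5.19, SE 0.20, edgeR adjusted p = 2.79e-08). Artn (artemin), a ligand of the GDNF family, rose from 0.564 ± 0.25 to 10.1 ± 0.24 CPM (log2 fold change 4.16, SE 0.23, edgeR adjusted p = 3.33e-07). Igf1 and Bdnf rose by log2 fold changes of 1.96 and 0.91 (edgeR adjusted p = 9.5e-05 and 3.56e-05). The log2 fold change of Gdnf, with 2.22 ± 0.69 CPM in rcMSC and 1.19 ± 0.31 in rbMSC, was 0.88 (edgeR adjusted p = 0.0341). Its call was lost without rbMSC replicate 1, rbMSC replicate 2, rcMSC replicate 1 or rcMSC replicate 3 (adjusted p = 0.116, 0.121, 0.0654 and 0.0652), and with the gene length trend removed (0.159). Lif, Nrg1 and Il6 fell by -1.10, -0.84 and -0.83. Vegfa (log2 fold change -0.05, edgeR adjusted p = 0.693) and Hgf (0.00, 0.998) did not pass. Without rcMSC replicate 3, Vegfa was at -0.17 with an adjusted p of 0.000171.

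The surface markers used to describe MSC were present in both groups. Thy1 had 505 ± 6.91 CPM in rcMSC and 1097 ± 14.4 in rbMSC (log2 fold change -1.12, edgeR adjusted p = 8.58e-08). Itgb1 was lower by -0.43 (edgeR adjusted p = 0.00325) and Cd44 higher by 0.58 (edgeR adjusted p = 6.12e-05). Of 18 surface markers, 4 were higher and 10 lower, 5 and 10 when adjusted over the list alone (camera adjusted p = 0.197). Mcam fell most, from 513 ± 14 to 27.2 ± 5.75 CPM (log2 fold change -4.24, edgeR adjusted p = 5.42e-08), and Vcam1 fell by -1.81.

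Markers of monocytes and macrophages, blood-derived cells that can persist in marrow cultures, were found in both groups and were lower in rcMSC. Of 25 tested, 20 were lower and 0 higher in edgeR, with a median of -0.85 (camera adjusted p = 4.93e-07), and the adjusted p = 0.0834 with an estimated correlation. Adjusted over the list alone, 22 were lower and 1 was higher. Ptprc (CD45) fell from 136 ± 4.88 to 45.6 ± 9.49 CPM (log2 fold change -1.57, edgeR adjusted p = 1.76e-05). Cd74 and RT1-Da, of class II antigen presentation, fell by -2.13 and -2.03. The 5 that did not pass were Cd14 (0.19), Fcer1g (0.08), Tyrobp (-0.29), Cd68 (-0.36) and Itgam (-0.47, edgeR adjusted p = 0.0537). Without rcMSC replicate 3, Itgam passed at -0.72 (adjusted p = 8.31e-12) and Fcer1g at 0.19 (0.0108), and without rcMSC replicate 1 Cd68 passed at -0.54 (0.0105). Of 8 osteoclast markers 1 was higher, Ctsk, and 2 lower, Tnfrsf11a and Itgb3 (-2.04 and -1.87), with 1 and 2 over the list alone (camera adjusted p = 0.676). None of the 16 lymphoid, neutrophil and erythroid markers in the table passed the low-count filter.

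Pericyte and contractile genes were lower in rcMSC. Of 10 pericyte markers, 8 were lower and 1, Anpep, was higher (log2 fold change 0.45), with 8 and 1 over the list alone and a median of -1.71 (camera adjusted p = 0.000373). For this list the adjusted p = 0.0834 with an estimated correlation. Rgs5, a signalling regulator of pericytes, fell from 9.49 ± 0.88 to 0.113 ± 0.036 CPM (log2 fold change -6.33, edgeR adjusted p = 2.63e-08), and Notch3 fell by -4.17. Of 19 smooth muscle and contractile genes, 14 were lower and 2 higher, 14 and 2 over the list alone, with a median of -0.93 (camera adjusted p = 2.25e-06, and the adjusted p = 0.0834 with an estimated correlation). Mylk, the myosin light chain kinase, fell from 302 ± 2.16 to 7.57 ± 0.80 CPM (log2 fold change -5.32, edgeR adjusted p = 6.51e-11), and Hspb7 fell by -4.84. The 2 that rose were Itga8 (0.81) and Synpo2 (0.63). Synpo2 did not pass without rbMSC replicate 1, rbMSC replicate 2, rcMSC replicate 1 or rcMSC replicate 2 (adjusted p = 0.0907, 0.0681, 0.0502 and 0.0815).

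Cell cycle genes were lower in rcMSC in 24 of 32 tested, with 0 higher in edgeR, and in 24 over the list alone. The median was -1.03 (camera adjusted p = 2.76e-08), and the adjusted p = 0.0824 with an estimated correlation. Cdc20 and Kif20a, which act in mitosis, fell by -1.59 and -1.57, and the proliferation marker Mki67 fell by -1.30. Pcna (-0.06, edgeR adjusted p = 0.573) did not pass. Hypoxia and glycolysis genes were lower in 12 of 19 and higher in 1, with 12 and 1 over the list alone and a median of -0.30 (camera adjusted p = 0.027, and the adjusted p = 0.177 with an estimated correlation). Ca9, a carbonic anhydrase, fell by -1.71 and the glycolytic enzyme Eno1 by -0.51. In the 1 that rose, the log2 fold change of Ankrd37 was 0.77 (edgeR adjusted p = 0.0449), and it did not pass without rbMSC replicate 1, 2 or 3 or rcMSC replicate 1 or 2 (adjusted p = 0.138, 0.091, 0.0616, 0.134 and 0.0834). It also did not pass with DESeq2 (adjusted p = 0.0996), without the low-count filter (0.0685) or with the length trend removed (0.0795).

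Genes of the skeletal lineages moved both ways. Of 19 osteoblast genes, 7 were higher and 9 lower, 7 and 9 over the list alone (camera adjusted p = 0.676). Dmp1, a matrix protein of osteocytes, had 208 counts in rbMSC and 2 in rcMSC, a ratio of 119 with an interval of 32.5 to 987. Ibsp (bone sialoprotein) fell by -5.97 (edgeR adjusted p = 2.21e-07), or -6.86 without rcMSC replicate 3, and Col1a1 rose by 0.84. Of 17 chondrocyte genes, 8 were higher and 7 lower, 8 and 8 over the list alone (camera adjusted p = 0.776). Col10a1 rose by 4.89 and Acan fell by -3.86, or -4.58 without rcMSC replicate 3. Of 18 adipocyte genes, 4 were higher and 8 lower, 4 and 9 over the list alone (camera adjusted p = 0.198). The lipid droplet protein Plin4 fell by -4.45 and Gpd1 by -3.20, or -3.89 without rcMSC replicate 3. Extracellular matrix genes were higher in 11 and lower in 21 of 43, and 11 and 21 over the list alone (camera adjusted p = 0.395), with Eln (elastin) at -4.81, Col18a1 at -4.14 and Aspn at 4.11. Matrix proteases and inhibitors were higher in 8 and lower in 11 of 26, with 8 and 11 over the list alone (camera adjusted p = 0.776). The collagenases Mmp13 and Mmp8 fell by -2.65 and -2.33.

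Signalling lists held large changes in both directions. Of 42 BMP and WNT signalling genes, 20 were higher and 8 lower, 20 and 10 over the list alone (camera adjusted p = 0.169). Sfrp2 rose by 6.70, while its relative Sfrp1 fell from 163 ± 1.56 to 3.41 ± 0.26 CPM (log2 fold change -5.58, edgeR adjusted p = 5.11e-11). Of 42 axon guidance genes, 16 were higher and 17 lower, 16 and 17 over the list alone (camera adjusted p = 0.857), with Sema3e at -2.20 and Plxnb1 at -1.70. Angiogenic and growth factors were higher in 6 and lower in 12 of 28, and 6 and 12 over the list alone (camera adjusted p = 0.157). Angptl4 fell by -3.97 and Fgf1 by -2.29. Of 18 inflammatory cytokines and chemokines, 2 were higher and 9 lower, 2 and 10 over the list alone. Their camera adjusted p was 0.0515, with 0.0316 when the gene length trend was removed, 0.0469 to 0.156 without 1 library and 0.295 with an estimated correlation. Cxcl12, a chemokine of the marrow niche, fell from 714 ± 13.6 to 51.9 ± 3.29 CPM (log2 fold change -3.78, edgeR adjusted p = 1.18e-10). Ccl20 rose by 3.28, or 4.02 without rbMSC replicate 3. Immunomodulatory factors were higher in 5 and lower in 7 of 17, and 5 and 7 over the list alone (camera adjusted p = 0.857), with Stc2 at 2.57 and Stc1 at 1.94. Here the median (-0.03) and camera pointed down, and fry pointed up.

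Of 21 ER and heat shock stress genes, 11 were higher and 6 lower, 12 and 6 over the list alone (camera adjusted p = 0.422), with a median of 0.21 and a mean of -0.07. The immediate early genes Fosb and Fos fell by -3.18 and -1.40, and Fosb by -3.77 without rcMSC replicate 3. Ddit3 and Atf4, of the ATF4 pathway, rose by 0.72 and 0.68. Senescence associated genes were higher in 6 and lower in 5 of 19, 6 and 6 over the list alone (camera adjusted p = 0.827), led by the binding proteins Igfbp6 (3.41) and Igfbp4 (1.35). Interferon response genes were higher in 4 and lower in 3 of 21, and 4 and 3 over the list alone (camera adjusted p = 0.422). Ifit2 rose by 1.06 and Mx1 fell by -1.10 (edgeR adjusted p = 0.0141), which did not pass without rbMSC replicate 2, rbMSC replicate 3 or rcMSC replicate 1 (adjusted p = 0.067, 0.0504 and 0.0555).

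Markers of other cell types showed no common direction. Of 11 neural lineage genes, 5 were higher and 4 lower, 5 and 4 over the list alone (camera adjusted p = 0.676), with Stmn2 at 1.57. Dcx, at 1.47 (edgeR adjusted p = 0.0194), did not pass without rbMSC replicate 2, rbMSC replicate 3, rcMSC replicate 1 or rcMSC replicate 2 (adjusted p = 0.0661, 0.0505, 0.0593 and 0.0603). Of 7 Schwann cell markers, 1 was higher and 3 lower, 1 and 3 over the list alone (camera adjusted p = 0.524), with S100b at -1.04 and Mbp at -0.81. Of 11 endothelial markers, 1 was higher, Tek (0.90), and 3 lower, Cd34 most (-1.78), with 1 and 3 over the list alone (camera adjusted p = 0.776). Of 14 meningeal fibroblast markers, 5 were higher and 6 lower, 5 and 6 over the list alone (camera adjusted p = 0.804), with Dpp4 at 3.63 and Aldh1a2 at -3.14. Their median was 0.14 and their mean -0.26. Of 5 keratinocyte and epithelial markers, 0 were higher and 2 lower in edgeR, 1 and 2 over the list alone (camera adjusted p = 0.94). These were Cdh1 (-1.86) and Sfn (-0.67), and Sfn did not pass without rbMSC replicate 1 or rcMSC replicate 1 (adjusted p = 0.0895 and 0.0663). The skeletal muscle list had 4 genes past the filter, too few to test as a list. Of these Myh3 rose by 4.20, or 5.15 without rbMSC replicate 2, and Acta1 fell by -1.91. No sex chromosome gene of the list passed the filter.

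The difference between the groups exceeded the spread within them. On the 500 most variable genes, principal component 1 held 94.5% of the variance and separated rcMSC from rbMSC. Those genes were picked by variance over all 6 libraries, which favours genes that differ between groups. With all genes kept, component 1 held 81.2%. Pearson correlations of log2 CPM were 0.996 between rbMSC libraries and 0.938 to 0.954 between groups. Within rcMSC, replicates 1 and 2 correlated at 0.997, and replicate 3 correlated with them at 0.988. Replicate 3 also had 20.1% of its counts in the 10 most abundant genes, against 17.4% and 17.5% in replicates 1 and 2 and 16.6% to 16.7% in rbMSC. Without rcMSC replicate 3, edgeR called 4512 genes higher and 4558 lower. The share in the 10 most abundant genes was 18.3% ± 1.53 in rcMSC and 16.6% ± 0.063 in rbMSC (n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). In the 50 most abundant genes the share was 29.0% ± 2.18 in rcMSC and 28.2% ± 0.109 in rbMSC (permutation p = 1), and rcMSC replicates 1 and 2, at 27.6% and 27.9%, lay below every rbMSC library. Genes with any count numbered 18588 ± 121 in rcMSC and 18897 ± 92.7 in rbMSC (permutation p = 0.1).

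**Figure D3:**
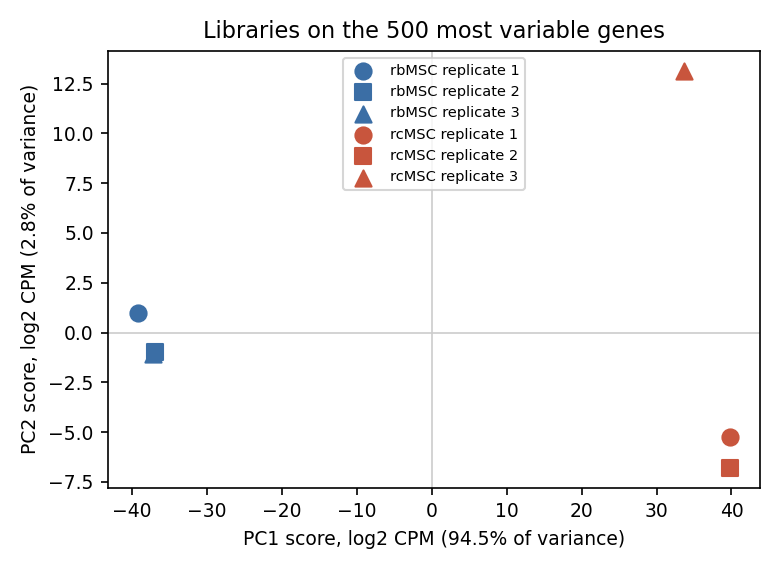
Scores of the 6 libraries on principal components 1 and 2 of log2 CPM, computed on the 500 most variable genes. The groups separate on component 1 (94.5% of variance), and rcMSC replicate 3 stands apart from rcMSC replicates 1 and 2 on component 2 (2.8%).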

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

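The tests in this part were chosen after the results were seen, except that of the class II genes outside the marker list, which was fixed before those genes were looked at. Counts on the 30 Y chromosome genes of the table were 4, 6 and 9 in rbMSC and 3, 12 and 8 in rcMSC replicates 1 to 3. The highest, 12, is above the 3 counts that a count of 0 allows, but is only 0.448 CPM over all 30 genes. No sex chromosome gene of the lists passed the low-count filter. As CPM the Y chromosome counts did not differ between the groups (0.288 in rcMSC and 0.269 in rbMSC, exact permutation p = 0.9).

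Replicate 3 of rcMSC lay apart from replicates 1 and 2, on the side of rbMSC. Unequal depth and a gene length trend are argued against: with all libraries thinned to 21340290 counts it still differed from replicates 1 and 2 by at least 12.7 times the chi-square per gene between them, and the length trend held 3.56% of the variance of its log2 differences. Mixed-in rbMSC RNA alone would give genes at least 8-fold higher in rbMSC the same mixing share as genes 2-fold to 8-fold higher. Medians were taken with 95% bootstrap intervals over genes, which are not independent. They were instead 1.98% (1.08 to 2.6) over 91 genes and 10% (8.19 to 11.7) over 680. Mixing as the only difference is thus argued against, while a small admixture beside another difference stays open. A difference between cultures or animals stays open, as the labels name none.

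Macrophage markers were lower in rcMSC, which a smaller share of the same macrophages could give. That would lower all markers alike, but 8 of the 25 tested lay over 0.5 (log2) and over 3 standard errors from the list's median, although some markers, such as Cd14, are also expressed by stromal cells. The 5 class II genes of the list had a median of -1.94 against -0.71 in the other 20 (exact one-sided permutation p = 0.00104 over genes, which are not independent), but they were singled out for their low values, so this p cannot count for a different macrophage state. In the test fixed beforehand, Ciita, RT1-DMa, RT1-DMb, RT1-DOb and RT1-Db2 had a median of -1.27 (exact one-sided permutation p = 0.0429 over genes, not adjusted for the other tests). This p rose to 0.0576 without rcMSC replicate 1 and 0.0758 without rcMSC replicate 2. As class II genes they are not independent of each other or of those in the list. A smaller share together with a change of state stays open: in rcMSC replicates 1 to 3 the ratio of Ptprc to Tyrobp counts was 4.27, 3.04 and 10.7 (11.3 to 13 in rbMSC), and that of Cd74 to Fcer1g 0.177, 0.15 and 0.292 (0.815 to 1.05 in rbMSC), where edgeR called Fcer1g higher without rcMSC replicate 3 (0.19) and not with all libraries (0.08).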

How the results depend on the processing

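No gene past the threshold was called in the opposite direction under any alternative. Values near 0 did change sign, and the log2 fold change of Vegfa was 0.03 without rcMSC replicate 2. Without 1 library the medians ranged from -0.22 to 0.22 for endothelial markers and -0.05 to 0.25 for meningeal fibroblast markers. They ranged from -0.17 to 0.08 for neurotrophic factors and -0.03 to 0.07 for axon guidance. With the length trend removed more genes were higher (3458) than lower (3268). Of the main calls, 2932 of 3351 higher and 3012 of 3445 lower genes were called again, so part of the calls depend on this trend. Without each library in turn, edgeR called 2542 to 4512 genes higher and 2794 to 4558 lower (at least 2-fold 752 to 1009 and 1206 to 1546, together 1978 to 2555), the highest without rcMSC replicate 3. Other scalings, filters, tools and dispersions gave 3062 to 4383 higher and 3268 to 4371 lower, the length trend, added after the data were seen, included. Against a 1.5-fold change, also added then, 802 were higher and 1213 lower, since smaller changes no longer count. With the replicate number as a block, 3046 were higher and 3251 lower (2088 at least 2-fold) and 7 lists passed. Deviations of libraries with the same number correlated at -0.027, 0.018 and -0.052, and those with different numbers at -0.058 to 0.064. No sign of pairing by number was seen, but a shared origin that leaves little common signal cannot be excluded this way. The 7 lists past camera's threshold, 1 higher and 6 lower, stayed past it in the alternatives run on lists (DESeq2 size factors, other filters, the block, a prior count of 0.5, the length trend, fry and each library left out) but not with the estimated correlation, where 0 passed (0 higher, 0 lower; 7 at an unadjusted p under 0.05), and fry called 22 (8 higher, 14 lower). The inflammatory list also passed without a low-count filter, with the length trend removed and without rcMSC replicate 1, so that the lists called ranged from 7 to 8 without 1 library. Component 1 held 81.2% of the variance with all genes, where none were picked by variance, and 89.8% with a prior count of 0.5. Why the share fell with the smaller prior count was not tested. Itgam, not past the threshold, passed in 6 alternatives, and Vegfa in 2. With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. Every other split mixes the 2 kinds of culture on both sides, so the difference between kinds becomes spread within sides. A count of 0 genes there was nearly fixed in advance and says nothing about chance. The real split gave 6796 changed genes (2119 at least 2-fold) and 7 lists, and the highest other 0, 0 and 7. The other splits called 4 to 7 lists. As large a result came from 1, 1 and 2 splits. Depth limits genes under about 1 CPM.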

Other observations

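The tests in this part were all chosen after the results were seen. Of 1359 gene ontology terms with 15 to 300 genes tested, 36 passed camera's threshold, 10 higher and 26 lower in rcMSC, and 0 passed with an estimated correlation (50 at an unadjusted p under 0.05, and 914 by fry). Translation led the higher terms, with 121 of 168 genes higher and 5 lower and a median of 0.80 (camera adjusted p = 1.26e-12, and the adjusted p = 0.858 with an estimated correlation). Among the lower terms were B cell receptor signaling (20 of 23 genes lower, camera adjusted p = 8.73e-08, and the adjusted p = 0.841 with an estimated correlation) and angiogenesis (75 of 162 lower, 29 higher, camera adjusted p = 0.0158, and the adjusted p = 0.841 with an estimated correlation).

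Of 61 genes with a ribosomal protein symbol that stands on 1 gene only, 60 were higher in rcMSC and 1, Rpl39l (-4.16), lower in edgeR, with a median of 1.07. They were picked by symbol, so genes named as ribosomal protein-like, such as Rpl10l, Rpl22l1, Rpl7l1 and Rpl39l, are among them. With the 40 further genes that share a symbol counted too, 95 of 101 were higher and 1 lower. The 61 held 1.22%, 1.26% and 0.812% of counts in rcMSC replicates 1 to 3, and 0.521%, 0.531% and 0.545% in rbMSC. The median stayed at 1.06 with DESeq2 size factors and with total count scaling. A gene length trend, with median changes from 0.286 in the shortest to -0.139 in the longest of 10 groups of genes, is argued against as the whole cause: 746 other genes matched on length and expression had a median of 0.244, which is 0.823 lower (95% bootstrap interval over genes 0.774 to 0.911). Genes are not independent, and the interval does not cover the spread between libraries. A single library is argued against too, with a median of at least 0.989 without each library in turn. Reads shared with ribosomal pseudogenes and a difference in growth between the cultures may contribute, and neither was tested directly. Cell cycle genes, however, were lower in rcMSC in 24 of 32 and higher in 0, with a median of -1.03 (-1.06 to -0.95 without 1 library). These values argue against faster division in rcMSC as the reason.

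Replicate 3 of rcMSC differed from replicates 1 and 2 in genes picked after their values were seen. It had 246 CPM of Spp1 (osteopontin) against a mean of 33 in the other rcMSC libraries. With all libraries Spp1 was at -2.63 and did not pass (edgeR adjusted p = 0.103). Without rcMSC replicate 3 it passed as lower in rcMSC, at -4.29 (edgeR adjusted p = 1.42e-56). That library was left out after its values were seen. Leaving it out lowered the median SD of log2 CPM within rcMSC from 0.156 to 0.0742, so the small p largely reflects the lost spread. Of 24 cholesterol biosynthesis genes, 22 were lower in replicate 3 than in the mean of replicates 1 and 2, by a median of -0.475. Between the groups, 9 of the 24 were higher and 2 lower in rcMSC in edgeR, and the term did not pass (camera adjusted p = 0.26).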
